A study of Mus musculus with 2 samples.

How the data were processed

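MicroRNA-seq counts were available for 2 libraries of E14.5 mouse lung, 1 per biological replicate. Per the labels, total RNA was used, the RNA fraction was under 30 nt and the strain was B6NCrl. The labels describe each sample as the lung of 1 pup and also give the sex as mixed, so whether a library holds tissue of more than 1 embryo was not settled. The authors deposited, for each library, a table of whole-number counts per miRNA gene in 3 columns, which on the values are counts without regard to strand, counts on the strand of the gene and counts on the opposite strand. For every gene the column without regard to strand equalled the sum of the other 2. Per the deposited readme, the counts derive from alignments to mm10 with GENCODE annotation M4. The aligner, the counter and their versions, adapter trimming and mismatch settings are not given in the sources used here. Counts were not normalized by the authors, judging from the differing totals. Each deposited table opens with 4 summary entries (unmapped, multimapping, no feature, ambiguous), which name no gene and stayed out of library sizes and tests. In replicate 1 they were 12.7%, 32.9%, 4.10% and 0% of reads, and in replicate 2 11.7%, 33.1%, 3.93% and 0%. Multimapping reads were not assigned to genes in the deposited counts, so genes whose mature sequence occurs at several loci lose reads.

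The gene-strand column was used, because the readme names no column and this one held the larger total (5128214 counts in replicate 1, 2332032 in replicate 2), by a rule fixed before the data were examined. Of 1973 genes, 1894 identifiers matched GENCODE M21, whose symbols, mm10 coordinates, strands and host genes were used, and the 79 unmatched ones held 1 gene-strand read in all. Hairpin sequences from the reference were used to mark genes that share 20 nt with another miRNA gene (923 genes) and for GC content. No column of per-sample values was left unused for lack of a sample (0 columns). Opposite-strand counts entered no main result. One count was 0.195 CPM in replicate 1 and 0.429 CPM in replicate 2.

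CPM were computed over gene-strand miRNA counts. Shares of 30 miRNA lists (families, clusters, cell types, imprinted loci and other tissues), fixed before the data were examined, were given with 95% exact (Clopper-Pearson) binomial intervals per library or as mean ± SD (n = 2). Ratios of lists used summed counts within a library. Agreement was measured with Pearson's r and Spearman's rho of log2(CPM + 1) over genes with at least 10 counts in both libraries, and with the common dispersion from edgeR. Log2 ratios are of replicate 2 to replicate 1 on TMM-scaled CPM with a pseudocount of 1 CPM. Each gene with at least 10 counts over both libraries was tested with an exact two-sided binomial test given the TMM-scaled library sizes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Such tests measure reads of these libraries and not a condition. A list with at least 3 tested members was placed as a percentile of its median log2 ratio among 10000 random lists of the same size matched on mean expression, as a description without a p-value. No test between groups was made, since there is 1 group.

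Genes named in the text were taken by a rule fixed before the data were examined: the 20 genes with the highest mean CPM, up to 4 members of each list with the highest mean CPM of at least 10 (for other tissues the highest member at any level), and the 5 highest and 5 lowest log2 ratios among genes with a mean of at least 100 CPM and an adjusted p under 0.05. Mir499, Mir206, Mir1a-1, Mir1b, Mir133b, Mir133a-1, Mir302b, Mir449c, Mir181a-2, Mir20b, Mirlet7a-2, Mir679, Mir24-2 and the opposite-strand loci fall outside it and were chosen after their values had been seen. The procedure was tested on simulated counts for the comparison of the replicates, with 407 genes tested and 200 genes changed. It recovered 77.6% of genes changed 2-fold and 70.8% of genes changed 1.41-fold, none (0) in the wrong direction, called 2 of 213 unchanged genes, placed a shifted list at percentile 100, and put 3 of 22 other lists outside the middle 95%. The simulated counts held counting error only, whereas the libraries also differed by a common dispersion of 0.033. These rates therefore do not measure performance on the libraries themselves.

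Alternatives fixed before the data were examined were other CPM denominators (without the most abundant gene, or with multimapping and other mapped unassigned reads), the unstranded column, leaving out each replicate, geometric means, lists without their most abundant member, other count filters and pseudocounts, library totals and DESeq2 size factors, summed list counts and other detection limits. Added after the data had been seen were a list without Mir208a, the common dispersion added to counting error through an exact beta-binomial test, and opposite-strand counts added to lists. Software was R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.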

Results

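MicroRNA sequencing (miRNA-seq), which reads the small RNA fraction to count microRNAs (miRNAs), was carried out on lung tissue of B6NCrl mouse embryos at embryonic day 14.5 (E14.5), a stage of airway branching. The 2 libraries formed 1 group, and the labels named no treatment, genotype or other stage, so the design holds no contrast between conditions. It allows a description of the miRNA composition of the lung, of ratios between miRNA groups within a library, and of how far the biological replicates differ. Per the labels each library came from a lung of a separate pup, although they also give the sex as mixed, so more than 1 embryo per library is not excluded. The labels give different collection days, so replicate and collection day cannot be told apart. Replicate 1 held 10200412 reads, of which 5128214 (50.3%) were counted on the strand of a miRNA gene. Replicate 2 was shallower, with 4544184 reads and 2332032 such counts (51.3%). Levels are given as counts per 1000000 gene-strand miRNA counts (CPM), as mean ± SD of the 2 libraries (n = 2). A gene with 0 counts could have held up to 3 counts, which is 0.585 CPM in replicate 1 and 1.29 CPM in replicate 2. Intervals and this floor cover counting error only, because amplified reads need not be independent molecules. Whether molecular identifiers were used is not known here.

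Among reads assigned to a single gene, the most abundant miRNAs of E14.5 lung were miRNAs of smooth muscle, of endothelium and of an imprinted host gene. Multimapping reads were assigned to no gene, so miRNAs with several copies could rank higher than counted. How readily each miRNA sequence was captured in a library was not measured, so ranks are those of reads. Mir143, a miRNA abundant in smooth muscle, was the most abundant gene at 69405 ± 12609.7 CPM (SD, n = 2). It was followed by Mir126a, the endothelial miRNA of the Egfl7 gene, at 67235 ± 12441 CPM, and by Mir335 at 64639 ± 5836 CPM. In mm10 coordinates Mir143 lies on chromosome 18 (61649196 to 61649258, minus strand). Mir126a lies on chromosome 2 (26591357 to 26591429, plus strand) within an annotated exon of Egfl7. Mir335 lies on chromosome 6 (30741299 to 30741396, plus strand) in an intron of the imprinted gene Mest. The place of Mir335 was not settled, since it ranked above the other 2 in replicate 2 (68765 CPM against 60488 for Mir143 and 58438 for Mir126a) and below them in replicate 1 (60512 against 78321 and 76033). Mir143 exceeded Mir126a in both libraries, by less than either gene differed between the libraries.

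The next genes in rank were Mirlet7g (51133 ± 303 CPM, in an intron of Wdr82), the X-linked Mir322 (46826 ± 5454) and Mirlet7i (39399 ± 4251). Mir10a of the HoxB region on chromosome 11 reached 37322 ± 2937 CPM, Mir99a 36995 ± 3187 and Mir17 35078 ± 8112. Mir26b (32468 ± 276), Mir23b (32119 ± 3179) and Mir130a (31709 ± 1486) followed. The remaining members of the top 20 were Mir30e, Mir99b, Mir20a, Mirlet7d, Mir429, Mir21a, Mir30a and Mir23a, from 23033 ± 4272 CPM for Mir30e to 11423 ± 663 CPM for Mir23a. The top 20 genes together held 66.5% ± 0.988 of counts (SD, n = 2), and 320 of the 1973 genes listed had at least 10 counts in both libraries. The top-20 share was 38.5% when multimapping and other mapped unassigned reads were put into the denominator, because 32.9% and 33.1% of reads were multimapping. Genes sharing 20 nt of hairpin sequence with another miRNA gene passed 10 counts in both libraries in 75 of 923 cases (8.13%), against 245 of 971 (25.2%) for the others, so members of multi-copy families are uncertain.

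**Figure D1:**
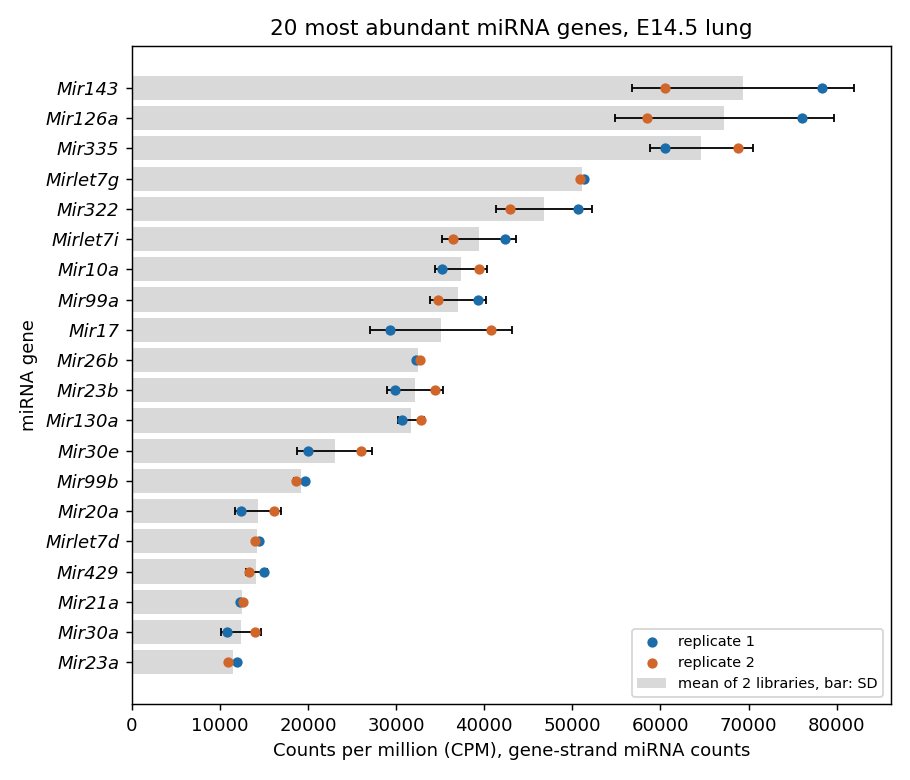
CPM (horizontal axis) of the 20 most abundant miRNA genes (vertical axis) in E14.5 lung, with 1 point per replicate, grey bars for the mean of the 2 libraries and error bars for the SD. Mir143 (69405 CPM), Mir126a (67235) and Mir335 (64639) lead, and the replicates lie far apart for Mir143, Mir126a and Mir17 but close together for Mirlet7g and Mir26b.

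Among miRNAs that mark cell types, the lists of endothelium and smooth muscle held more counts than the epithelial miR-200 family, each through 1 gene, and blood miRNAs were scarce. Mir126a, the measured member of the endothelial list, held 6.72% ± 1.24 of counts (n = 2). The smooth muscle list held 7.09% ± 1.26, nearly all of it Mir143, with Mir145a from the same cluster at 1502 ± 45.8 CPM. Without Mir143 the smooth muscle share was 0.161%, below that of the miR-200 family. The 5 members of the epithelial miR-200 family, which restrain the mesenchymal regulators Zeb1 and Zeb2, were all detected and together held 3.35% ± 0.0308. Within that family Mir429 (14134 ± 1153 CPM) and Mir200c (10881 ± 969) exceeded Mir200b (5942 ± 308) and Mir141 (1643 ± 116) in both libraries. The list of stratified and sensory epithelium held 1.53% ± 0.221, with Mir182 at 6454 ± 1970 CPM, Mir183 at 2893 ± 19.03, Mir205 at 2380 ± 229 and Mir203 at 2100 ± 90.9. The mesenchymal miR-199 and miR-214 list held 0.966% ± 0.0829, most of it Mir214 (8920 ± 692 CPM) from the Dnm3os transcript on chromosome 1, while Mir199b (631 ± 109) and Mir199a-2 (107 ± 22.8) share sequence with other copies. The multiciliated cell list held 0.202% ± 0.0387, through Mir449a (1106 ± 525 CPM, in an intron of Cdc20b) and Mir34c (881 ± 142).

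Blood miRNAs were present at low levels. The erythroid list held 0.0455% ± 0.00715 of counts, with Mir451a at 367.5 ± 38.2 CPM and Mir144 at 76.6 ± 36.2 CPM. The white blood cell list held 0.0848% of counts in the mean of both libraries, led by the myeloid Mir223 at 564 ± 34.8 CPM, followed by Mir146 (171 ± 21.01), Mir155 (76.0 ± 18.1) and Mir150 (36.2 ± 3.93). That list rose to 0.158% when counts on the strand opposite to Mir142b, where the annotation places Mir142, were added after the data had been seen.

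Several lists set up beforehand for other tissues gave small but measurable shares. Whether their reads came from cells of the lung or from other tissue was not tested. The neuroendocrine and pancreatic list held 0.355% ± 0.0197 (n = 2), almost entirely Mir375 (3408 ± 208 CPM), a miRNA of endocrine cells located on chromosome 1 (74900658 to 74900721, minus strand). The neuronal list held 0.0727% ± 0.00389, led by Mir132 (375 ± 13.0 CPM) and Mir137 (82.5 ± 5.73). Of its 14 listed members 11 share 20 nt with another hairpin and can lose multimapping reads. Its share could therefore be higher than counted, and which member leads is uncertain. The gut and kidney list held 0.015% ± 0.00122, from Mir192 (74.0 ± 10.6 CPM) and Mir194-2 (73.2 ± 20.8). Of its 4 listed members 2 share 20 nt in this way, Mir194-2 among them. The hepatocyte miRNA Mir122 stood at 30.9 ± 12.04 CPM, a share of 0.00309% ± 0.0012. The striated muscle list held 0.0214% ± 0.0221, an SD above its mean, because its most abundant member Mir208a stood at 299 CPM in replicate 1 and 11.6 CPM in replicate 2.

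The let-7 family, whose levels climb during differentiation in many tissues, held the largest share of the 30 lists, at 11.96% ± 0.498 of counts over 10 members, all of them detected. Besides Mirlet7g and Mirlet7i, its leading members were Mirlet7d (14184 ± 316 CPM) and Mir98 (7892 ± 330, in an intron of Huwe1). The miR-17~92 cluster and its paralogous clusters, known to promote proliferation of lung progenitors, held 8.09% ± 1.31 over 15 members, all detected, with Mir17, Mir20a (14271 ± 2627 CPM), Mir93 (10139 ± 2020) and Mir106b (8415 ± 389) in front. By contrast the miR-302 and miR-367 cluster of pluripotent cells held 0.00452% ± 0.0016, and its leading members Mir302a and Mir302d stood at 17.98 ± 2.98 and 16.1 ± 7.01 CPM. The miR-99, miR-100 and miR-125 clusters held 6.25% ± 0.367, the miR-23/24/27 clusters 4.73% ± 0.198, the miR-30 family 4.13% ± 0.753 and the miR-26 family 3.25% ± 0.0268. The miR-15/16 family held 1.49% ± 0.0266 and the miR-181 family 1.48% ± 0.229, led by Mir181c (5546 ± 353 CPM) and Mir181d (5304 ± 1287). Mir21a (12443 ± 184 CPM, in the Vmp1 gene) and the hypoxia-induced Mir210 (441 ± 17.7) together held 1.29% ± 0.0166. The miR-29 family was low at 0.0166% ± 0.00111, with Mir29a at 97.6 ± 9.49 CPM and Mir29c at 67.0 ± 2.01. Family totals are lower bounds where copies share their mature sequence, as for Mir26a-1 (21.2 ± 3.92 CPM) and Mir26a-2 (55.6 ± 3.49). In the miR-181 family 4 of 6 members share 20 nt with another hairpin, so the lead of Mir181c and Mir181d is uncertain.

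Imprinted and X-linked clusters were prominent. The Dlk1-Dio3 locus on chromosome 12, whose miRNAs are transcribed from the maternal allele, held 6.45% ± 0.306 of counts (n = 2), and 39 of its 43 listed members had at least 10 counts in both libraries. Its leading members were Mir411 (8925 ± 2330 CPM), Mir127 (8075 ± 11.2), Mir487b (6354 ± 179) and Mir379 (5938 ± 1230). In mm10 they lie on the plus strand between 109592846, the start of Mir127, and 109727414, the end of Mir487b. The share was 7.56% when opposite-strand counts at 4 further loci of the region were added, a choice made after the data had been seen. The X-linked miR-322 and miR-503 cluster held 5.83% ± 0.557, with Mir322 ahead of Mir351 (8083 ± 1.24 CPM), Mir503 (1914 ± 87.6) and Mir542 (1051 ± 5.92). The Sfmbt2 intron cluster on chromosome 2 held 0.384% ± 0.00894, led by Mir467e (1125 ± 6.52 CPM), although 67 of its 69 listed members share sequence with another hairpin. Mir483, in an intron of the imprinted Igf2 gene, stood at 1068 ± 25.04 CPM and Mir675, in an exon of H19, at 91.4 ± 8.44, a joint share of 0.116% ± 0.00166.

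**Figure D2:**
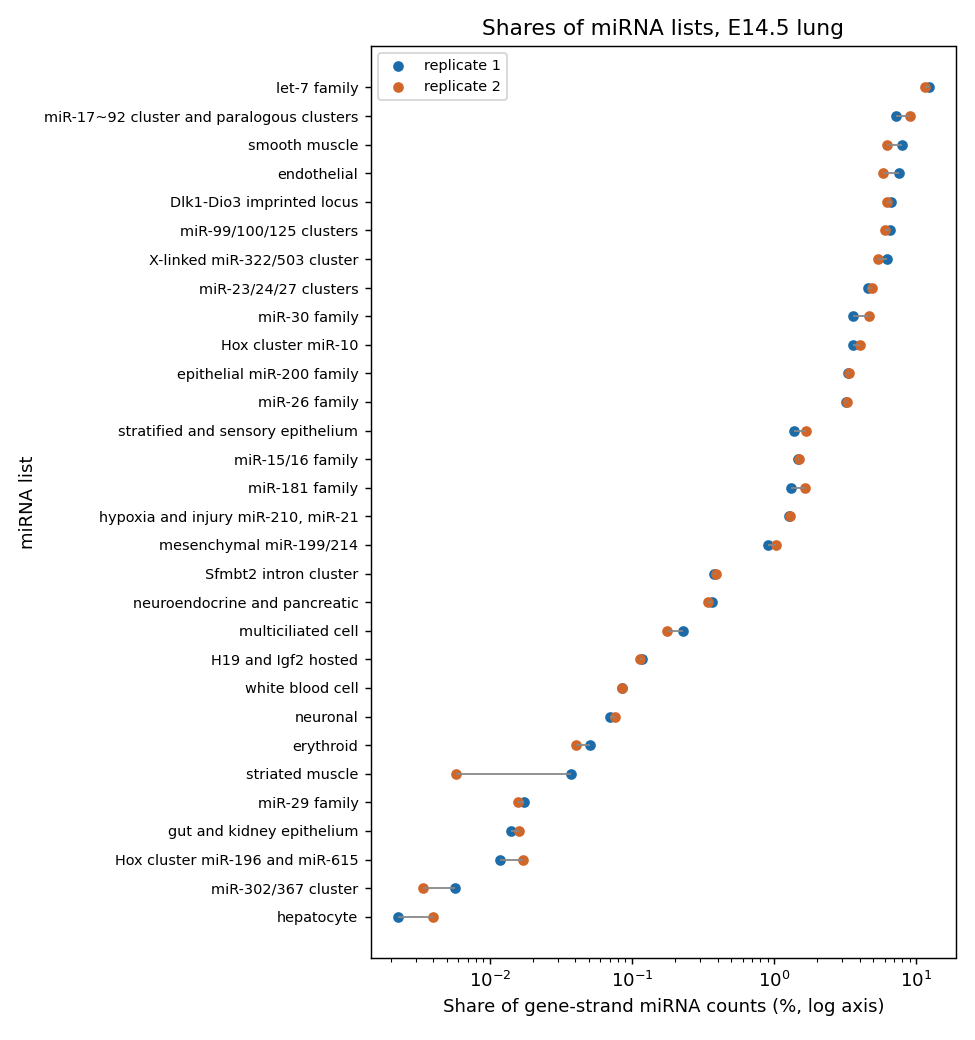
Share of gene-strand miRNA counts (percent, horizontal log axis) held by each of the 30 miRNA lists (vertical axis) in the 2 replicates, 1 point per replicate joined by a line. The let-7 family holds the highest share in both (12.3% and 11.6%), and the striated muscle list has the widest gap (0.037% and 0.00575%).

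Ratios between lists were taken within each library, without any scaling between libraries. They compare read counts of different sequences, and how evenly those sequences were captured was not measured. Uneven capture shared by both libraries would repeat in both ratios. The Hox-embedded miR-10 genes exceeded the Hox miRNAs miR-196 and miR-615 by 306-fold in replicate 1 and 233-fold in replicate 2, a log2 ratio of 8.06 ± 0.27 (SD, n = 2). Mir10a accounted for most of the former, with Mir10b, in the HoxD region, at 600.1 ± 51.9 CPM. Mir615 (77.8 ± 0.307 CPM, in an intron of Hoxc5), Mir196b (53.6 ± 35.8, at Hoxa9) and Mir196a-2 (10.7 ± 1.29) were far lower. The list of miR-196 and miR-615 held 0.0144% ± 0.00384 of counts against 3.79% ± 0.299 for the miR-10 list. The mesenchymal miR-199 and miR-214 list lay 3.67-fold and 3.29-fold below the epithelial miR-200 family, a log2 ratio of -1.80 ± 0.11. The let-7 family exceeded the miR-17~92 group by 1.72-fold and 1.29-fold, a log2 ratio of 0.57 ± 0.29. Each of these 3 ratios kept its side of 0 in both libraries, but an exact two-sided sign test on 2 libraries cannot go below p = 0.5, so none is reported. Copies lose multimapping reads unequally, since 3 of 4 members of the miR-199 and miR-214 list share 20 nt with another hairpin against 0 of 5 of the miR-200 family, so the level of the former is a lower bound and which list was higher is not settled by these counts. Such members were 5 of 10 for let-7 and 4 of 15 for miR-17~92, and 2 of 4 for miR-196 and miR-615 and 0 of 2 for miR-10. The sizes rest on single members and on how members are combined: without the most abundant member of each list the miR-10 ratio was 3.30 and the miR-199 and miR-214 ratio -4.71, and with geometric means the latter was -4.12 and the let-7 ratio 1.28.

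The replicates ranked miRNA genes in nearly the same order, with moderate differences in level. Across the 320 genes with at least 10 counts in both libraries, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.992 and Spearman's rho 0.991. The median absolute log2 ratio between replicates was 0.21, its 90th percentile 0.58, and 90.3% of these genes lay within 1.5-fold. Mir130a (log2 ratio of replicate 2 to replicate 1 of 0.01), Mir145a (-0.03) and Mir487b (-0.03) were close to equal. Beyond 2-fold lay 10 genes, of which 8 were higher in replicate 1, among them Mir208a, Mir449a, Mir144 and Mir208b, and 2 higher in replicate 2, among them Mir196b. The common dispersion from edgeR was 0.033, a biological coefficient of variation of 18.2%.

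Many abundant miRNAs differed between the 2 libraries by more than counting error. Of 404 genes tested, 169 (41.8%) passed an adjusted p of 0.05 in exact two-sided binomial tests, 72 higher in replicate 2 and 97 higher in replicate 1. Mir208a, a cardiac miRNA in an intron of Myh6 (alpha myosin heavy chain; chromosome 14, 54949060 to 54949142, minus strand), had 1533 counts in replicate 1 and 27 in replicate 2, a log2 ratio of -4.66 (exact binomial adjusted p = 6.89e-217). Mir449a, of multiciliated cells, was lower in replicate 2 with a log2 ratio of -1.10 (exact binomial adjusted p = 4.32e-204). The other genes lowest in replicate 2 among those of at least 100 CPM were Mir411 (-0.63), Mir27a (-0.62) and Mir369 (-0.61). Those highest in replicate 2 were Mir181b-2 (0.79), Mir362 (0.63), Mir541 (0.61), Mir182 (0.54) and Mir667 (0.44). The most abundant genes were among those that passed, with Mir143 at -0.46, Mir126a at -0.47 and Mir17 at 0.39. Below 100 CPM, Mir196b was higher in replicate 2 (log2 ratio 1.36), while Mir144 (-1.08) and Mir302d (-0.94) were lower.

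These tests compare 2 libraries, not conditions, and with the common dispersion of the same libraries added to counting error, a choice made after the data had been seen, 1 gene passed, Mir208a (exact test, adjusted p = 1.54e-21). The split of calls depended on scaling: with library totals 112 genes were higher in replicate 2 and 65 in replicate 1, and with DESeq2 size factors 61 and 107, since TMM and DESeq2 scaling shifted all log2 ratios by -0.09 and -0.14 relative to library totals.

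**Figure D3:**
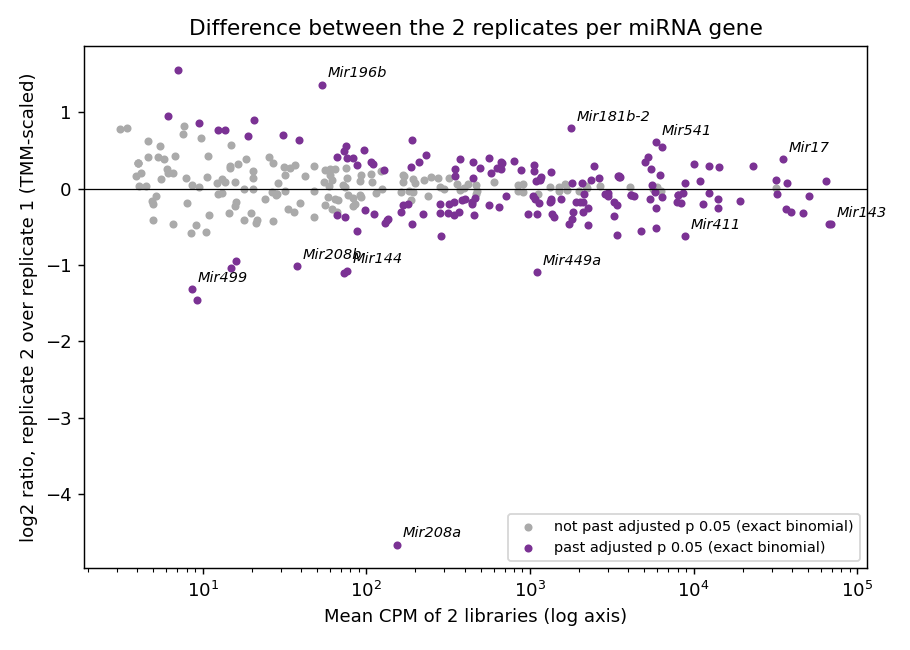
Log2 ratio of replicate 2 to replicate 1 after TMM scaling (vertical axis) against mean CPM of the 2 libraries (horizontal log axis), 1 point per miRNA gene, purple where the exact binomial test passed an adjusted p of 0.05 and grey otherwise. Mir208a stands alone at -4.66, and Mir181b-2 has the highest ratio (0.79) among genes of at least 100 CPM.

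Some miRNA lists lay apart from random lists between the replicates. Single calls were common among abundant genes, since 138 of 187 genes of at least 100 CPM passed the same test, so the number of members called does not set a list apart. The miR-17~92 group was higher in replicate 2, at 9.02% of counts (95% exact binomial interval 8.98 to 9.05) against 7.16% (7.14 to 7.19). Of its 15 members 9 differed, 7 of them higher in replicate 2 (9 when adjusted over the list alone), among them Mir17 (0.39), Mir93 (0.32) and Mir20a (0.29), while Mir106b was lower (-0.18). The median log2 ratio of the group was 0.27, at percentile 99.9 of 10000 random lists matched on size and mean expression. The miR-181 family also lay high, with a median of 0.23 (percentile 99.3). All 6 members differed, 4 higher and 2 lower in replicate 2 (6 when adjusted over the list alone). Mir181b-2 (0.79) and Mir181d (0.41) lay above and Mir181a-1 (-0.18) below. Of the 6 members 4, among them Mir181b-2 and Mir181a-1, share 20 nt with another hairpin. Their ratios rest on the reads left after multimapping reads were set aside.

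The lists of striated muscle, multiciliated cells and the miR-302 and miR-367 cluster lay low in replicate 2. The striated muscle list held 0.037% of counts in replicate 1 (exact interval 0.0354 to 0.0387) and 0.00575% in replicate 2 (0.00481 to 0.00681). Its median log2 ratio of -1.02 lay below all random lists. Of 5 members tested 4 differed (4 when adjusted over the list alone): Mir208a, Mir208b of the Myh7 intron (-1.02) and Mir499 (-1.32) were lower in replicate 2, whereas the skeletal muscle miRNA Mir206 was higher (0.86). Without Mir208a, a choice made after the data had been seen, the median was -0.72 (percentile 0.23). The multiciliated list had a median of -0.52 (percentile 0.045), but of its 5 members 2 differed (2 when adjusted over the list alone) and in opposite directions, Mir449a lower and Mir34c higher (0.24) in replicate 2. Its median gene, Mir449c, had 11 and 3 counts. The miR-302 and miR-367 cluster had a median of -0.68 (percentile 0.17), with 2 of 4 tested members lower in replicate 2 (2 when adjusted over the list alone), Mir302d (-0.94) and Mir302b (-1.46).

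Together 5 of 23 lists lay outside the middle 95% of random lists. If list members varied independently, 1.15 would fall there by chance, and 3 of 22 unshifted lists fell there in simulated counts of independent genes. Members of families and clusters need not vary independently, so 1.15 is no firm expectation for these lists. The miR-181 family no longer lay outside when list counts were summed (percentile 94.7), and the miR-23/24/27 clusters (median -0.31, percentile 2.6) did so with library totals (2.13) and with DESeq2 size factors (2.28). With summed counts the Dlk1-Dio3 locus (log2 ratio -0.19, below all random lists), miR-196 and miR-615 (0.46, percentile 99.1) and the miR-30 family (0.28, percentile 98.0) also lay outside, against percentiles of 18.2, 94.0 and 93.7 for their medians. Members moved in both directions in some of the other lists and in 1 direction in others. In the let-7 family 7 of 10 members differed (8 when adjusted over the list alone), 2 higher and 5 lower in replicate 2, and the list median of -0.04 (0.05 with library totals) lay at percentile 51.6. At the Dlk1-Dio3 locus 24 of 40 tested members differed (26 when adjusted over the list alone), 7 higher and 17 lower in replicate 2, with Mir541 (0.61) and Mir667 (0.44) at one end and Mir411 (-0.63), Mir369 (-0.61) and Mir379 (-0.52) at the other. All 4 members of the miR-199 and miR-214 list were higher in replicate 2 (4 when adjusted over the list alone), with a median of 0.30 at percentile 95.3, but the summed counts, mostly those of Mir214 (0.07), gave 0.09 at percentile 72.2. In the X-linked miR-322 and miR-503 cluster 5 of 7 members were lower in replicate 2 (5 when adjusted over the list alone), led by Mir322 (-0.33), with a median of -0.19 at percentile 8.36, although with library totals Mir351 was equal (8082 and 8084 CPM). In the miR-30 family Mir30a (0.29), Mir30d (0.26) and Mir30e (0.29) were higher and the other 3 members did not pass (3 of 6 also when adjusted over the list alone). In the epithelial miR-200 family 2 of 5 members differed (2 when adjusted over the list alone), Mir429 lower (-0.26) and Mir200c higher (0.09) in replicate 2.

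**Figure D4:**
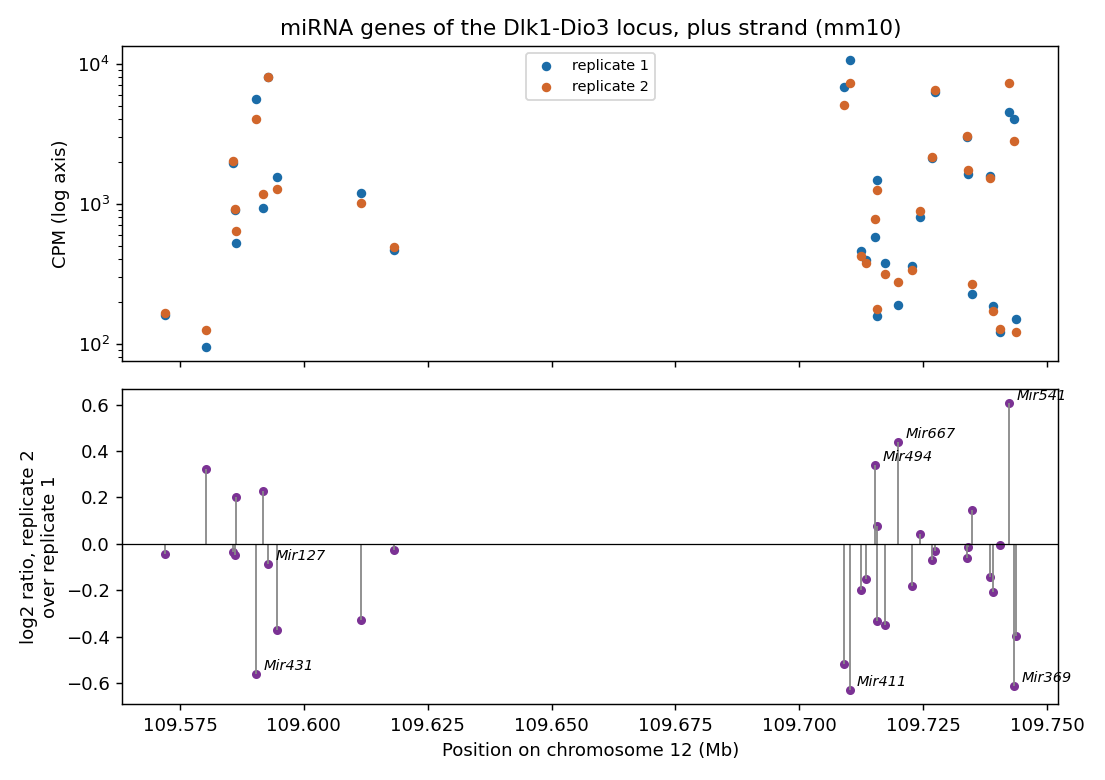
MicroRNA genes of the Dlk1-Dio3 locus with a mean of at least 100 CPM by position on chromosome 12 (horizontal axis, Mb, mm10, plus strand), with CPM per replicate above (log axis) and the TMM-scaled log2 ratio of replicate 2 to replicate 1 below. Neighbouring genes differ in both directions, such as Mir541 (0.61) and Mir369 (-0.61).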

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

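All tests in this part were chosen after the results had been seen. Counts outside the main measurement stood far above the limit of 3 counts. The opposite-strand column held 150350 counts in replicate 1 and 67687 in replicate 2, and 3359798 and 1503822 reads were multimapping. The opposite-strand counts were concentrated at Gm24321 (mean of 5927 CPM over the 2 libraries), Gm25927 (5166), Gm25301 (4984), Gm25252 (2912), Mir299b (2772), Gm24083 (2717), Mir497b (1926) and Gm25750 (1682), with lower levels at Mir142b (775), Gm24111 (196) and Mir3074-1 (75.5).

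Strand leakage of the protocol and reads of a miRNA on the other strand were weighed for these opposite-strand counts. Leakage was argued against, because the highest opposite-strand share among 131 other genes with at least 1000 gene-strand counts per library was 0.484%, while the lowest share at the 11 loci was 48.7%, both over the summed libraries (53.1% and 39.1% per library at that locus, Mir3074-1). At each of the 11 loci the M21 annotation places another miRNA on the counted strand that was not analysed here: Mir409, Mirlet7e, Mir378a, Mir376a, Mir299a, Mir191, Mir497, Mir380, Mir142, Mirlet7f-1 and Mir24-1, in the order of the loci above. These loci held 99.9% of all opposite-strand counts (99.8707%), which is consistent with reads of those miRNAs, a hypothesis formed on the same data. No biological explanation was tested, since the design has 1 group.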

How the results depend on the processing

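The common dispersion added to counting error, the opposite-strand counts added to lists and the list without Mir208a were chosen after the data had been seen, and the other alternatives before. The top-20 share of 66.5% was 64.0% without the most abundant gene in numerator and denominator, 38.5% with mapped unassigned reads in the denominator and 64.7% in the unstranded column, all by construction of the total. The log2 ratio of miR-10 to miR-196 and miR-615 was 3.30 without the most abundant members. That of miR-199 and miR-214 to miR-200 was -4.71 without them and -4.12 with geometric means, and that of let-7 to miR-17~92 was 1.28 with geometric means; these follow from the weight of single members, and no ratio changed sign. With no count filter the median absolute log2 ratio was 0 and Spearman's rho 0.897, since 1285 genes had 0 counts in both libraries. With the common dispersion added, 1 gene differed, by construction of the wider error. At 1 count in both libraries 541 genes were detected. Numbers of lists outside the random range were 6, 6, 7 and 5 with library totals, DESeq2 size factors, summed counts and without Mir208a. List shares moved beyond 1 SD for 29 of 30 lists with unassigned reads, 15 without the most abundant gene and 7 in the unstranded column. In these settings CPM moved for 92, 37 and 14 of 98 named genes, and adding opposite-strand counts moved 3 of 5 lists. Pseudocounts of 0.1 and 10 CPM, and a minimum of 100 counts in both libraries, left the correlations and the median absolute log2 ratio within the limits set for a change. With at least 100 counts summed over the libraries 164 genes differed. Leaving out either replicate gave top-20 shares of 65.8% to 67.2% and turned none of the 3 list ratios. Depth limits genes near the floor of 0.585 and 1.29 CPM, and 2 libraries limit every spread given. No paired analysis was possible because there is 1 group.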

Other observations

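The tests of GC content and of counting error were chosen before the results they measure were seen, and the other tests in this part after. Cardiac miRNAs stood out between the replicates. Mir208a, of the alpha myosin heavy chain gene Myh6, was 27.5-fold higher in replicate 1 after TMM scaling. Mir208b, of Myh7, was 2.06-fold higher and Mir499 2.81-fold higher, with 64 and 11 counts. These folds were taken without the pseudocount that the log2 ratios carry. Mir206 had 32 and 30 counts. The measured miR-1 and miR-133 genes were barely counted, with 1 and 0 counts for Mir1a-1 and 10 and 3 for Mir1b. Mir133b had 3 and 3 counts, and Mir133a-1, whose copies share their mature sequence and so lose multimapping reads, had 0 in both libraries. These genes belong to the striated muscle list, fixed before the data were examined. The cardiac subset, however, was chosen after the values had been seen, and Mir206 and Mir133b of that list had log2 ratios of 0.86 and 0.49. Of the 9 listed members of the striated muscle list 4 share 20 nt with another hairpin and can lose multimapping reads. Low counts of the miR-1 and miR-133 genes therefore need not mean that these miRNAs were scarce.

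Depth as the cause was argued against for Mir208a, since the lowest log2 ratio among the other genes of at least 100 CPM was -1.10 against -4.66 for Mir208a. The comparison does not cover Mir208b and Mir499, which lay under 100 CPM. Whether heart tissue, alone or on top of a baseline in both libraries, gave these counts stays open. Mir208a (1533 and 27 counts) and Mir208b (256 and 60) changed in different ratios (exact two-sided Fisher test p = 1.01e-28, which covers counting error only), but their proportion in heart tissue was not measured, so unequal ratios exclude no heart source. The log2 ratios of Mir499 and Mir208b lay at percentiles 0.625 and 2.19 among genes with at least 10 counts in both libraries, which restates the pattern and decides nothing. Adjoining heart muscle taken with the lung of replicate 1, or cardiac muscle within lung veins, may be the source as a hypothesis, and the collection day differed as well.

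Neighbouring miRNAs moved apart between the replicates in some clusters and together in others, with a mean difference between members above 0.3 (log2) in 16 of 31 clusters. Mir541 and Mir369 had log2 ratios of 0.61 and -0.61, Mir181b-2 and Mir181a-2 of 0.79 and -0.42, and Mir143 and Mir145a of -0.46 and -0.03. By contrast 5 genes of the X-linked cluster lay between -0.33 (Mir322) and -0.09 (Mir351), and Mir23a, Mir24-2 and Mir27a at -0.21, -0.31 and -0.62. Counting error was argued against over all pairs of genes within the 31 clusters (104 genes), whose median difference was 6.29 times that expected from it. Most of these pairs lie at the Dlk1-Dio3 locus, so that value speaks mainly for this locus. Hairpin GC content was argued against by a rank correlation of -0.0462 across genes, which are not independent replicates (permutation p = 0.523). Transcription of whole clusters as the main source was argued against, because the mean difference within clusters was 1.06 times (bootstrap interval 0.865 to 1.31) that of shuffled clusters.

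Genes at different loci with similar hairpins differed less. Over 42 pairs sharing at least 14 nt and lying on different chromosomes or over 1 Mb apart, the mean difference was 0.622 times that of shuffled genes (one-sided permutation p = 0.0256). It was 0.609 times at 12 nt, 0.501 times at 16 nt, and 0.637 times over 47 pairs when 5 pairs within the Sfmbt2 intron were included. The shuffled genes included Mir208a (log2 ratio -4.66), which is in none of the 42 pairs and raises the shuffled mean. The ratio of 0.622 is therefore lower than it would be without Mir208a, and the test was not run without that gene. Mir30a, Mir30d and Mir30e (0.29, 0.26 and 0.29), Mir20a and Mir20b (0.29 and 0.34), and Mir99a and Mir100 (-0.27 and -0.26) lay close, while Mir23b and Mir23a (0.11 and -0.21), Mirlet7d and Mirlet7a-2 (-0.14 and 0.29), and Mir679 and Mir449a (0.08 and -1.10) lay apart. The sign was shared by 61.9% of the 42 pairs, against 50.1% of all pairs. Some paired genes, such as Mir23b and Mir23a, share 20 nt with another hairpin and can lose multimapping reads. Such pairs compare the reads left, not all reads of a shared sequence, so they do not test its capture directly. A candidate explanation is that capture of a miRNA depends on its sequence and differed between the library preparations, which may also bear on the shift of the miR-17~92 group. Regulation shared by related genes, or cell types that express them together, stays open, since no test here separates it from capture.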
